A study of Homo sapiens with 9 samples.

How the data were processed

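RNA was measured in 9 libraries of RBE cells, 3 for each of the lentiviral hairpins (a scramble control, shIDH1 and shJOSD2). Per the labels' protocols, poly(A) RNA was selected from total RNA with oligo(dT) beads, made into strand-marked cDNA libraries by the dUTP method with unique molecular identifiers in the adapters, and sequenced as read pairs on an Illumina NovaSeq. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, UMI-tools and StringTie 1.3.4d were used with the genome build GRCh38. The role of each tool, the annotation release, the counting step and its strand setting are not given in the sources used here, so it is unknown whether the molecular identifiers were used to remove duplicates.

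The deposited table holds 36225 Ensembl genes with a count and an FPKM value for each library. The counts deposited by the authors are whole numbers that were not normalized, per the file headers. The FPKM values deposited by the authors are per the file headers, where the unit stands for fragments scaled by transcript length and library size. Low counts gathered at 4, 8, 12 and 16, so 1 sequenced fragment seems to carry about 4 counts, as a count derived from coverage would give. This is an inference from the values. Totals lay between 66036276 and 71612713 counts per library, and counting error is larger than the counts themselves imply. Pairs of replicates differed well beyond sampling noise, with a chi-square of 3.62 to 10.0 per degree of freedom after division by 4, and none was counted as a repeated library.

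The design fixed before the data were examined assumed FPKM values. Since the table also held counts, edgeR 4.0.16 in R 4.3.3 was used for the main tests, and limma 3.58.1 on log2 FPKM became an alternative. All 9 libraries entered 1 fit with a mean per group and no block. Genes were kept by filterByExpr (21492 genes), libraries were scaled by TMM, and genes were tested by quasi-likelihood F-tests with Benjamini-Hochberg adjustment over all tested genes at 0.05. Standard errors are the absolute log2 change over the square root of F. FPKM means and SDs are over the 3 libraries of a group. Single values of IDH1 and JOSD2 were also tested by exact permutation. Where a group was at 0, a bound was computed against 12 counts over its 3 libraries.

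A set of 36 gene lists with 635 distinct genes was fixed before the data were examined. Of these genes, 628 matched a gene of the table and 613 were tested. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 36 lists. Fry does not set the members against other genes, and is reported for the YAP/TAZ list and the lists called in opposite directions. With the estimated correlation, 3 lists were called in shIDH1 cells, 0 in shJOSD2 cells and 3 between the hairpins, against 20, 20 and 14 with the preset one. The lists overlap in part. Named genes were chosen by a rule fixed before the data were examined: IDH1, JOSD2, IDH2, JOSD1, ATXN3, YAP1 and WWTR1, the 10 largest fitted rises and falls per comparison with control and 5 between hairpins among called genes with a symbol and separate FPKM ranges, up to 4 called members with the largest change per list, the genes called by both hairpins with the largest smaller fitted change, the whole YAP/TAZ signature, and the most abundant markers of other cell types and RNA quality. APOE, GSTP1, LDHB, HBA2, HBA1, EVI2B and genes of KEGG terms in the closing section were chosen after their values were seen. A few genes that this selection held are not reported here.

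The edgeR step was tested on simulated counts for the real genes, of which 19808 passed the filter. For shIDH1 against control it recovered 49.2% of 61 genes changed 1.5-fold, 77.6% of 76 changed 2-fold and 96.8% of 63 changed 4-fold, with 12 false calls among 162. For shJOSD2 against control it recovered 39 of 65, 51 of 68 and 63 of 67 such genes, with 13 false calls among 166. Alternatives were DESeq2 1.42.0, other filters, scalings, variance models, a replicate block, limma on FPKM and TPM, and each library left out in turn. Limma on log2(FPKM + 1), the test the design named for FPKM values, was kept as an alternative once the counts were found. Counts divided by 4, library sizes without TMM factors and control replicate 1 as the lone control were added after seeing the data. With the lone control, that library was assumed to vary like those of the other groups. GC content and length of the longest transcript came from GENCODE transcripts for 98.2% of tested genes. Figures were drawn with matplotlib 3.10.9.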

Results

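Gene expression was measured by poly(A) RNA sequencing in RBE cells, an established human line of intrahepatic cholangiocarcinoma, a cancer of the bile ducts inside the liver. The cells had been infected with lentivirus carrying a scramble control (control), a short hairpin RNA against IDH1 (shIDH1) or a short hairpin RNA against JOSD2 (shJOSD2), with 3 libraries per group and 9 in all. IDH1 encodes the cytosolic NADP-dependent isocitrate dehydrogenase, and JOSD2 a Josephin-domain deubiquitinase. The series title names mutant IDH1, JOSD2 and YAP/TAZ, the transcriptional coactivators encoded by YAP1 and WWTR1. Library totals lay between 66036276 and 71612713 deposited counts, at roughly 4 counts per sequenced fragment. The labels do not say whether the libraries of a group came from separate infections, so the p-values measure only the spread between these libraries, which may be technical.

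The targeted genes were examined first. IDH1 (ENSG00000138413; GRCh38 chromosome 2, 208236229 to 208266074, minus strand) stood at 44.0 ± 4.44 FPKM in control, 12.6 ± 0.446 in shIDH1 and 34.5 ± 1.56 in shJOSD2 libraries (SD, n = 3 each). JOSD2 (ENSG00000161677; chromosome 19, 50505998 to 50511191, minus strand) stood at 6.37 ± 0.260 FPKM in control, 1.68 ± 0.174 in shIDH1 and 0.795 ± 0.101 in shJOSD2 libraries (SD, n = 3 each). Each hairpin thus went with a lower level of its target in every library, IDH1 by 3.48-fold and JOSD2 by 8.52-fold. IDH1 fell by 1.80 ± 0.07 on the log2 scale in shIDH1 cells (SE; adjusted p = 1.85e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). JOSD2 fell by 3.09 ± 0.17 in shJOSD2 cells (adjusted p = 1.08e-07, the same edgeR test with Benjamini-Hochberg adjustment). JOSD2 also fell in shIDH1 cells, to a level 3.73-fold lower than in control (adjusted p = 7.69e-07, edgeR with Benjamini-Hochberg adjustment), and stood 2.29-fold higher there than in shJOSD2 cells (adjusted p = 7.16e-05, the same test). IDH1 fell by 0.50 ± 0.07 in shJOSD2 cells (adjusted p = 8.66e-05, edgeR with Benjamini-Hochberg adjustment). The JOSD2 values in shJOSD2 libraries rest on 72 to 89 deposited counts each. Exact two-sided permutation tests of the FPKM values gave p = 0.1 for both genes in each comparison, the smallest p that 3 against 3 libraries allow.

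**Figure D1:**
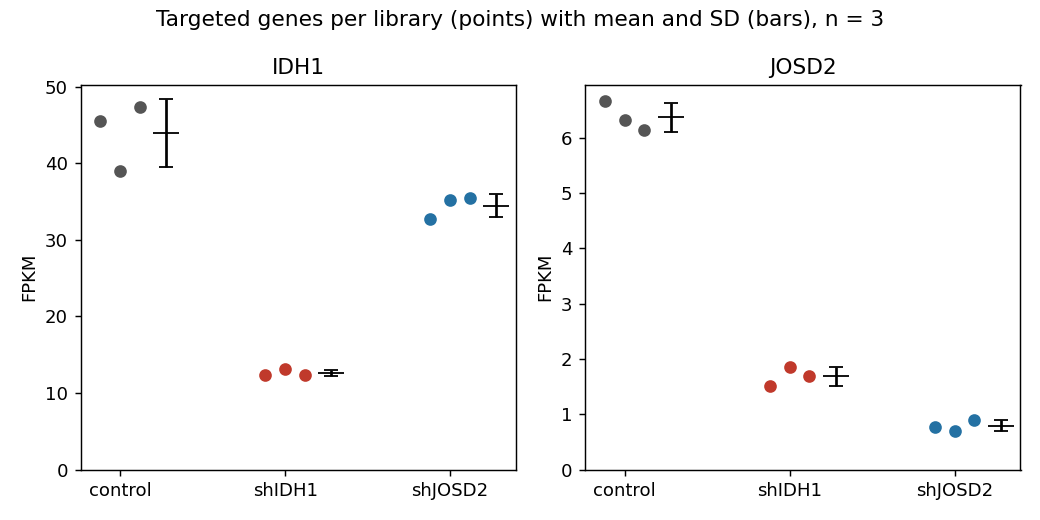
FPKM of IDH1 and JOSD2 in each of the 9 libraries (points), with the mean and SD of each group of 3 (black bars). IDH1 had its lowest values in the shIDH1 libraries, 12.3 to 13.1 FPKM, and JOSD2 in the shJOSD2 libraries, 0.708 to 0.906 FPKM.

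The comparison of shIDH1 with control asks which transcripts change when IDH1 is depleted. Genes of mitosis and DNA replication fell furthest among the gene groups tested. KIF20A, a mitotic kinesin, fell by 4.27 ± 0.16 on the log2 scale (SE, n = 3 per group), from 24.7 ± 3.20 to 1.28 ± 0.331 FPKM, and AURKB, CDC20 and UHRF1 fell with log2 changes of -4.16 ± 0.18, -4.16 ± 0.14 and -4.21 ± 0.26. SPARC, a matricellular protein, rose by 5.03 ± 0.15, from 0.766 ± 0.191 to 25.3 ± 2.10 FPKM, and the YAP/TAZ target ANKRD1 rose 22.3-fold, from 52.4 ± 7.10 to 1166 ± 42.4 FPKM. FGB, which encodes a fibrinogen chain, rose by 4.65 ± 0.09. In all, edgeR's quasi-likelihood test called 10769 of 21492 tested genes at a Benjamini-Hochberg adjusted p under 0.05, 5258 higher and 5511 lower, of which 4120 changed at least 2-fold. The FPKM ranges of the groups did not overlap for 56.9% of tested genes, where chance gives 10%.

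All 25 genes of the G2/M and mitosis list fell, with a median log2 change of -3.14 (camera, adjusted p = 2.37e-58, and adjusted p = 0.0483 with an estimated correlation), and all 25 passed adjusted over the list alone. All 25 genes of the S phase and DNA replication list fell as well, 25 adjusted over the list alone, with a median of -2.47 (camera, adjusted p = 1.24e-35, and adjusted p = 0.105 with an estimated correlation). Among them RRM2, a subunit of ribonucleotide reductase, fell by 3.59 ± 0.22 and the helicase gene MCM4 by 3.35 ± 0.17. All 24 genes of cholesterol synthesis fell, 24 adjusted over the list alone, with a median of -1.95 (camera, adjusted p = 1.71e-23, and adjusted p = 0.114 with an estimated correlation). MVK, encoding mevalonate kinase, fell by 2.83 ± 0.12, INSIG1 by 2.58 ± 0.18 and EBP by 2.55 ± 0.08. Of 17 genes of fatty acid synthesis 15 fell and 1 rose, 16 adjusted over the list alone, with a median of -1.12 (camera, adjusted p = 8.40e-11, and adjusted p = 0.0483 with an estimated correlation). ACSS2, an acetyl-CoA synthetase, fell from 54.9 ± 11.7 to 10.4 ± 1.67 FPKM.

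Genes of central metabolism had smaller median changes. Of 20 glycolysis genes 13 fell and 5 rose, 18 adjusted over the list alone, with a median of -0.58 (camera, adjusted p = 2.85e-05, and adjusted p = 0.308 with an estimated correlation). PGAM1 fell by 1.74 ± 0.07 and PKM, a pyruvate kinase, was 2.46-fold lower. Of 21 genes of the TCA cycle and isocitrate dehydrogenases 16 fell, IDH1 included, and 2 rose, 18 adjusted over the list alone, with a median of -0.41 (camera, adjusted p = 2.85e-05, and adjusted p = 0.290 with an estimated correlation). OGDH, a subunit of the 2-oxoglutarate dehydrogenase complex, fell by 1.66 ± 0.06, and IDH2 had a log2 change of -0.05 ± 0.07 that did not pass the test. Of 24 nuclear-encoded respiratory chain genes 18 fell, 18 adjusted over the list alone, with a median of -0.39 (camera, adjusted p = 0.000362, and adjusted p = 0.497 with an estimated correlation). Of 23 proteasome genes 17 fell and 1 rose, 18 adjusted over the list alone, with a median of -0.29 (camera, adjusted p = 0.00580, and adjusted p = 0.585 with an estimated correlation). Over 5 other scalings the least negative medians were -0.29 for the TCA cycle, -0.27 for the respiratory chain and -0.17 for the proteasome list.

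Several stress-response groups rose. Of 22 genes of the ATF4 and amino acid response 13 rose and 3 fell, 16 adjusted over the list alone, with a median of 0.66 (camera, adjusted p = 0.000392, and adjusted p = 0.497 with an estimated correlation). DDIT3, a stress-induced transcription factor, rose by 3.36 ± 0.17 and GDF15, a stress-induced cytokine, from 79.6 ± 11.2 to 605 ± 86.3 FPKM. Of 16 genes of ER stress and protein folding 12 rose and 1 fell, 14 adjusted over the list alone, with a median of 0.52 (camera, adjusted p = 0.000362, and adjusted p = 0.497 with an estimated correlation). HSPA5, the ER chaperone BiP, rose by 1.88 ± 0.19 and HERPUD1 by 2.29 ± 0.19. Of 19 NRF2 targets 13 rose and 5 fell, 19 adjusted over the list alone, with a median of 0.76 (camera, adjusted p = 0.00133, and adjusted p = 0.497 with an estimated correlation). HMOX1, heme oxygenase, rose by 3.68 ± 0.34 and the aldo-keto reductase gene AKR1C1 by 3.10 ± 0.12. Of 19 p53 targets 14 rose and 3 fell, 17 adjusted over the list alone, with a median of 0.62 (camera, adjusted p = 9.92e-05, and adjusted p = 0.249 with an estimated correlation), among them SESN2 by 2.06 ± 0.14 and BBC3 by 1.96 ± 0.12. Of 18 hypoxia targets 10 rose and 4 fell, 14 adjusted over the list alone, with a median of 0.45 (camera, adjusted p = 0.0105, and adjusted p = 0.176 with an estimated correlation), with ADM up by 2.09 ± 0.09 and VEGFA by 1.44 ± 0.08. Of 22 immediate early genes 13 rose and 6 fell, 19 adjusted over the list alone, with a median of 0.49 (camera, adjusted p = 0.0253, and adjusted p = 0.308 with an estimated correlation). Of 20 apoptosis regulators 9 rose and 4 fell, 13 adjusted over the list alone, with a median of 0.22 (camera, adjusted p = 0.0253, and adjusted p = 0.176 with an estimated correlation).

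Of 16 mesenchymal genes 11 rose and 2 fell, 13 adjusted over the list alone, with a median of 0.58 (camera, adjusted p = 1.67e-07, and adjusted p = 0.111 with an estimated correlation). LOXL2, a lysyl oxidase, rose by 1.75 ± 0.09 on the log2 scale. Of 17 biliary lineage genes 11 rose and 2 fell, 13 adjusted over the list alone, with a median of 0.33 (camera, adjusted p = 0.000297, and adjusted p = 0.0833 with an estimated correlation), SPP1 among them by 2.16 ± 0.10. Of 8 fibroblast markers 5 rose and 1 fell, 6 adjusted over the list alone, with a median of 1.31 (camera, adjusted p = 0.0253, and adjusted p = 0.176 with an estimated correlation). The lowest median of this list over 5 other scalings was 0.79. Its most abundant member ACTA2 stood at 27.3 ± 1.15 FPKM against 12.8 ± 1.02 in control. Of 9 nuclear-retained and non-polyadenylated RNAs, listed as a sign of RNA quality, 5 rose and 1 fell, 6 adjusted over the list alone, with a median of 0.60 (camera, adjusted p = 0.0493, and adjusted p = 0.308 with an estimated correlation). This call was lost without control replicate 3, shIDH1 replicate 3 or shJOSD2 replicate 1, with camera adjusted p values of 0.0700, 0.0558 and 0.0510.

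The 10 falls and 10 rises ranked first by fitted change among called genes with separate FPKM ranges all had a group at 0 counts. Their order is not measured and they are not shown to be the largest changes, since the measured folds of KIF20A and SPARC exceed most of the bounds below. Against a floor of 12 deposited counts over the 3 libraries, or about 3 fragments, LIX1 and CEACAMP10 were at least 42.2-fold and 35.2-fold higher in shIDH1 cells, and the other 8 that rose (F13B, PIK3C2G, TIE1, ITGAD, LINC02680, LINC00536, SCN1A and COL9A1) at least 12.6-fold to 25.8-fold. Those that fell were GET1-SH3BGR, CBLC, IHH, TMSB15A, ARHGDIG, MARCO, VGLL1, IGFL1, CSTF3-DT and CEACAM5, at least 6.58-fold to 15.9-fold lower, of which CBLC, VGLL1 and CEACAM5 were not called against control replicate 1 alone. All 20 lay below 1 FPKM in both groups. GET1-SH3BGR is a read-through locus, CEACAMP10 a pseudogene and CSTF3-DT a divergent transcript, so counts shared with neighbouring or similar genes leave their values uncertain.

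The remaining lists did not pass the test in shIDH1 cells. Called members rose and fell, respectively, for 10 and 5 of 23 Hippo pathway components, 9 and 7 of 19 2-oxoglutarate-dependent chromatin demethylases, 7 and 5 of 28 interferon-stimulated genes, 9 and 3 of 14 class I antigen presentation genes, 1 and 6 of 18 NF-kB targets, 6 and 7 of 20 epithelial adhesion genes, 5 and 3 of 11 Notch targets, and 7 and 5 of 15 TGF-beta targets. The corresponding numbers were 3 and 6 of 25 cytosolic ribosomal proteins, 3 and 9 of 13 housekeeping controls, 3 and 1 of 13 mitochondrial transcripts, and 1 and 2 of 3 Josephin-domain deubiquitinases. Adjusted over the list alone, 16, 17, 12, 12, 6, 16, 8, 12, 8, 12, 4 and 3 members passed, in the same order. Among the 4 other marker lists, 3 of 11 leukocyte genes fell and 3 of 7 endothelial genes rose, while 2 and 1 of 7 HEK293T or other line genes and 4 and 7 of 20 hepatocyte genes rose and fell, with 3, 4, 3 and 11 passing adjusted over the list alone. The median and mean were negative but the test pointed up for interferon-stimulated, hepatocyte and HEK293T genes, and the Notch list had a median of 0.05, a mean of -0.01 and a test pointing up. The housekeeping list had a camera adjusted p of 0.0844, and 0.0380 without control replicate 1. WWC1, which encodes the Hippo pathway scaffold KIBRA, rose by 1.15 ± 0.06 and VGLL4, a TEAD cofactor, fell by 1.24 ± 0.07. JOSD1 fell by 0.49 ± 0.06 and ATXN3 rose by 0.43 ± 0.12, a call that ended with control replicate 1 as the lone control (adjusted p = 0.231, edgeR with Benjamini-Hochberg adjustment).

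Some hepatocyte transcripts were uneven among the control libraries themselves, with 7 of the 20 list members at least 4-fold higher in both control replicates 2 and 3 than in replicate 1. APOA1, the main apolipoprotein of high-density lipoprotein, stood at 2.91 FPKM in control replicate 1, 40.0 in replicate 2 and 45.5 in replicate 3, against 2.51 to 6.24 in the 6 knockdown libraries. ALB, encoding albumin, stood at 0.104, 1.23 and 1.43 FPKM in the same control libraries, and at 0.122 to 0.269 in the knockdown libraries. Other members did not follow, as FGB stood at 1.53, 1.72 and 1.87 FPKM, FGA at 1.03, 1.14 and 1.93 and SERPINA1 at 33.6, 37.8 and 33.9 in control replicates 1, 2 and 3. With control replicate 1 as the lone control, the counts of called genes were 8476 for shIDH1 and 5569 for shJOSD2, and all 20 lists called for shIDH1 and 19 of the 20 called for shJOSD2 remained called. The hepatocyte list, not called against all 3 control libraries (camera, adjusted p = 0.0844 for shIDH1 and 0.518 for shJOSD2, and 0.0108 for shIDH1 without control replicate 3), gave adjusted p values of 3.02e-05 and 0.000541 against that library alone, with medians of 0.74 and 0.62. Mitochondrial transcripts were also called in shJOSD2 cells against that library (camera, adjusted p = 0.00995). The median of the epithelial adhesion list in shJOSD2 cells moved from -0.57 to 0.01 against that library, that of the mesenchymal list from 0.58 to 1.04 in shIDH1 and from 0.20 to 0.57 in shJOSD2 cells, that of the biliary list in shIDH1 cells from 0.33 to 0.51 and that of the proteasome list there from -0.29 to -0.15. In shJOSD2 cells the medians of the NRF2, YAP/TAZ and Josephin-domain lists moved from -0.37 to -0.21, from 0.29 to 0.18 and from -0.25 to -0.43.

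The comparison of shJOSD2 with control asks which transcripts change when JOSD2 is depleted. Cholesterol synthesis genes fell together: MVD, a decarboxylase of the mevalonate pathway, fell by 2.44 ± 0.08 on the log2 scale (SE, n = 3 per group), to 10.8 ± 0.496 FPKM, 5.41-fold lower, and LSS, lanosterol synthase, by 2.07 ± 0.08. Mitotic genes fell too, PLK1 by 2.47 ± 0.15 and KIF20A by 2.12 ± 0.14, and KIF20A fell further in shIDH1 cells, with a log2 difference of -2.15 ± 0.15 between the hairpins (adjusted p = 2.44e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). BIRC3, an inhibitor of apoptosis induced by NF-kB, fell by 2.83 ± 0.12, and the glycolytic genes PFKP and ENO1 by 2.24 ± 0.08 and 2.16 ± 0.08. The transcription factor gene SNAI2 rose by 1.93 ± 0.09 and the cytokine gene CSF1 by 1.56 ± 0.10. In all, edgeR's quasi-likelihood test called 8237 of 21492 genes at a Benjamini-Hochberg adjusted p under 0.05, 3907 higher and 4330 lower, of which 2328 changed at least 2-fold. The FPKM ranges of the groups did not overlap for 51.7% of tested genes, where chance gives 10%. The share of higher calls depended on the scaling: library sizes without TMM factors shifted the median of all genes to 0.18 and gave 5638 higher and 2934 lower, and limma on log2(FPKM + 1) gave 4150 higher and 2843 lower.

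All 24 cholesterol synthesis genes fell, 24 adjusted over the list alone, with a median of -1.51 (camera, adjusted p = 1.39e-36, and adjusted p = 0.156 with an estimated correlation). All 17 fatty acid synthesis genes fell, 17 adjusted over the list alone, with a median of -0.66 (camera, adjusted p = 1.12e-15, and adjusted p = 0.0657 with an estimated correlation), with SCD, a stearoyl-CoA desaturase, down by 1.58 ± 0.11 and FASN, the fatty acid synthase, by 1.33 ± 0.08. All 25 G2/M genes fell, 25 adjusted over the list alone, with a median of -1.55 (camera, adjusted p = 2.77e-33, and adjusted p = 0.156 with an estimated correlation). Of 25 S phase genes 24 fell, 24 adjusted over the list alone, with a median of -1.36 (camera, adjusted p = 5.09e-22, and adjusted p = 0.191 with an estimated correlation), with CCNE2, a cyclin, down by 2.58 ± 0.24. Of 20 glycolysis genes 13 fell and 2 rose, 15 adjusted over the list alone, with a median of -0.36 (camera, adjusted p = 2.05e-09, and adjusted p = 0.191 with an estimated correlation). Of 21 TCA cycle and isocitrate dehydrogenase genes 13 fell and 2 rose, 16 adjusted over the list alone, with a median of -0.40 (camera, adjusted p = 9.78e-05, and adjusted p = 0.345 with an estimated correlation), and IDH2 rose by 0.23 ± 0.07, a call lost without control replicate 1 or 3 or without shJOSD2 replicate 2 or 3 (adjusted p = 0.0782, 0.0633, 0.0546 and 0.104, edgeR with Benjamini-Hochberg adjustment). Of 23 proteasome genes 16 fell, 17 adjusted over the list alone, with a median of -0.32 (camera, adjusted p = 2.47e-06, and adjusted p = 0.348 with an estimated correlation). Of 24 respiratory chain genes 11 fell, 11 adjusted over the list alone, with a median of -0.17 (camera, adjusted p = 0.00897, and adjusted p = 0.617 with an estimated correlation), but 1 of 5 other scalings turned that median to 0.04 and it was -0.03 against the lone control. The least negative medians over these scalings were -0.44 for fatty acid synthesis, -0.21 for glycolysis, -0.16 for TCA cycle and isocitrate dehydrogenase genes and -0.12 for proteasome genes.

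The ATF4, ER stress, NRF2, NF-kB, apoptosis and epithelial adhesion lists were lower in shJOSD2 cells by camera with its preset correlation. Of 22 ATF4 and amino acid response genes 15 fell and 4 rose, 20 adjusted over the list alone, with a median of -1.04 (camera, adjusted p = 2.37e-06, and adjusted p = 0.348 with an estimated correlation). ASNS, asparagine synthetase, fell by 1.92 ± 0.15 and PSAT1, of serine synthesis, by 1.87 ± 0.12. Of 16 ER stress genes 9 fell and 1 rose, 11 adjusted over the list alone, with a median of -0.39 (camera, adjusted p = 0.0192, and adjusted p = 0.668 with an estimated correlation). Of 19 NRF2 targets 10 fell and 3 rose, 13 adjusted over the list alone, with a median of -0.37 (camera, adjusted p = 0.0106, and adjusted p = 0.596 with an estimated correlation), NQO1 among them by 1.59 ± 0.10. Of 18 NF-kB targets and cytokines 12 fell and 1 rose, 13 adjusted over the list alone, with a median of -1.04 (camera, adjusted p = 2.90e-05, and adjusted p = 0.156 with an estimated correlation). Of 20 apoptosis regulators 10 fell and 4 rose, 15 adjusted over the list alone, with a median of -0.26 (camera, adjusted p = 0.0290, and adjusted p = 0.191 with an estimated correlation). Of 20 epithelial adhesion genes 9 fell, 12 adjusted over the list alone, with a median of -0.57 (camera, adjusted p = 0.00159, and adjusted p = 0.348 with an estimated correlation), with the desmosomal gene DSP down by 1.83 ± 0.07. The epithelial median lay at -0.08 in the least negative of 5 other scalings and at 0.01 against control replicate 1 alone. The limma fits among these scalings also leave out members with a mean FPKM under 1. The least negative medians over those scalings were -0.18 for ER stress, -0.17 for NRF2 and -0.03 for apoptosis genes.

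Of 19 p53 targets 14 rose, 16 adjusted over the list alone, with a median of 0.44 (camera, adjusted p = 1.15e-05, and adjusted p = 0.191 with an estimated correlation). Of 16 mesenchymal genes 7 rose and 3 fell, 10 adjusted over the list alone, with a median of 0.20 (camera, adjusted p = 0.00950, and adjusted p = 0.348 with an estimated correlation). Of 8 fibroblast markers 3 rose and 1 fell, 4 adjusted over the list alone, with a median of 0.59 (camera, adjusted p = 0.0167, and adjusted p = 0.191 with an estimated correlation), and PDGFRB rose by 2.51 ± 0.23 to 2.81 ± 0.125 FPKM. Of 13 housekeeping controls 9 fell, 9 adjusted over the list alone, with a median of -0.31 (camera, adjusted p = 0.00338, and adjusted p = 0.348 with an estimated correlation), ACTB by 0.99 ± 0.09. In the least negative of 5 other scalings the housekeeping median was -0.09, so most of it depended on the scaling or on the other steps of that fit. The 3 Josephin-domain genes were called as a list (camera, adjusted p = 0.0411, and adjusted p = 0.287 with an estimated correlation), but JOSD2 was the 1 member called, also adjusted over the list alone, and the median of the list lay between -0.26 and -0.06 over the other scalings. Without control replicate 1 that list and the apoptosis list had camera adjusted p values of 0.0889 and 0.0501 and were no longer called.

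The 10 rises and 10 falls ranked first by fitted change in shJOSD2 cells again had a group at 0 counts and lay below 1 FPKM. They are not shown to be the largest changes, and the measured fall of BIRC3 exceeds all 10 bounds of the falls. CYP4F23P, DMRT1, COL6A5, MYBPC1, COL19A1, MCF2, PIK3C2G, KRT79, OSTCP1 and HAS2-AS1 were at least 7.88-fold to 18.5-fold higher. HOXB7, CXCL5, NOP53-AS1, BCL2L14, TMC5, ZBTB16, TAC4, YBX2, RFPL3S and IL34 were at least 2.91-fold to 6.45-fold lower. Of these 20, COL19A1, MCF2 and the falls other than NOP53-AS1 and RFPL3S were not called against control replicate 1 alone, and YBX2 and IL34 also lost their call without control replicate 2 or 3 or any 1 shJOSD2 replicate (adjusted p = 0.0547 to 0.0935 and 0.0556 to 0.0680, edgeR with Benjamini-Hochberg adjustment). CYP4F23P and OSTCP1 are pseudogenes, and NOP53-AS1, HAS2-AS1 and RFPL3S are antisense genes whose counting by strand is not given in the sources used here.

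For the lists that did not pass in shJOSD2 cells, called members rose and fell, respectively, for 4 and 7 of 23 Hippo pathway components, 4 and 0 of 19 chromatin demethylases, 6 and 3 of 18 hypoxia targets, 3 and 6 of 28 interferon-stimulated genes, 5 and 4 of 14 class I antigen presentation genes, 4 and 10 of 22 immediate early genes, 5 and 8 of 17 biliary genes, 3 and 2 of 11 Notch targets, and 4 and 7 of 15 TGF-beta targets. Adjusted over the list alone, 12, 4, 10, 9, 9, 16, 13, 5 and 13 members passed, in the same order. For cytosolic ribosomal proteins 1 rose and 4 fell of 25, for mitochondrial transcripts 2 rose of 13, for nuclear-retained RNAs 4 rose of 9, for hepatocyte genes 5 rose and 7 fell of 20, and for leukocyte markers 3 fell of 11. Of 7 HEK293T or other line markers 1 rose. Of 7 endothelial markers edgeR's quasi-likelihood test called 0 (3 at an unadjusted p under 0.05), and limma called 0 on log2(FPKM + 1) and 1 on quantile-normalized values. Adjusted over the list alone, 2, 2, 5, 13, 3, 0 and 0 members of these 7 lists passed. The test pointed up for hepatocyte genes despite a negative median and mean, and up for Notch targets and down for interferon-stimulated and ribosomal genes, whose medians were positive and means negative. Nuclear-retained RNAs had a camera adjusted p of 0.0790, and 0.0474 without control replicate 2. Mitochondrial transcripts made up 9.72% ± 0.461 of counts in control, 11.0% ± 0.123 in shIDH1 and 11.7% ± 0.684 in shJOSD2 libraries (SD, n = 3 each).

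Both hairpins were then set side by side. Of the genes called in either comparison, 5102 changed in the same direction in both, 2367 higher and 2735 lower, and 967 changed in opposite directions. Cell cycle and cholesterol genes made up part of the shared falls, as KIF20A and INSIG1 above, while TXNIP, an arrestin-family regulator of glucose uptake, fell by 1.93 ± 0.13 in shIDH1 cells and rose by 2.29 ± 0.13 in shJOSD2 cells. FUT1, a fucosyltransferase gene, rose by 1.86 ± 0.36 in shIDH1 cells and fell by 1.76 ± 0.39 in shJOSD2 cells, the fall not being called against control replicate 1 alone (adjusted p = 0.103, edgeR with Benjamini-Hochberg adjustment). Ranked by the smaller fitted change, PIK3C2G, COL9A1, F13B, CYP4F23P and COL6A5 came first among the shared rises and SLC12A3, HOXB7, NXPH2, BGN and TKTL1 among the shared falls, all below 1 FPKM in every group. The 5 rises had control at 0 counts, and these ranks rest on few counts and are not measured. By DESeq2 the falls of NXPH2 and BGN were not called in either comparison. Leaving out 1 library ended both calls of SLC12A3, NXPH2 and BGN and the shIDH1 call of HOXB7, with highest adjusted p values of 0.0718, 0.124 and 0.131 without control replicate 3 and 0.0858 without shIDH1 replicate 2. Against control replicate 1 alone these 5 falls were not called in either, and TKTL1, at 0.121, 1.20 and 1.39 FPKM in control replicates 1, 2 and 3, had log2 changes of -0.75 in shIDH1 and -0.69 in shJOSD2 cells. Independent lists of these sizes would share 2066 genes in the same direction. In 20 simulations of unchanged groups against shared control libraries, the mean was 0.05 genes and the highest 1. With no changed genes, hardly any gene passes the adjusted threshold in such simulations. They therefore do not measure how many of the 5102 genes the shared controls add. The log2 fold changes correlated across genes, which are not independent replicates, with Pearson's r = 0.607 against 0.491 in the simulations, and their covariance was 0.882 against 0.0997, a difference of 0.783. The 3 control libraries cannot be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls.

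**Figure D2:**
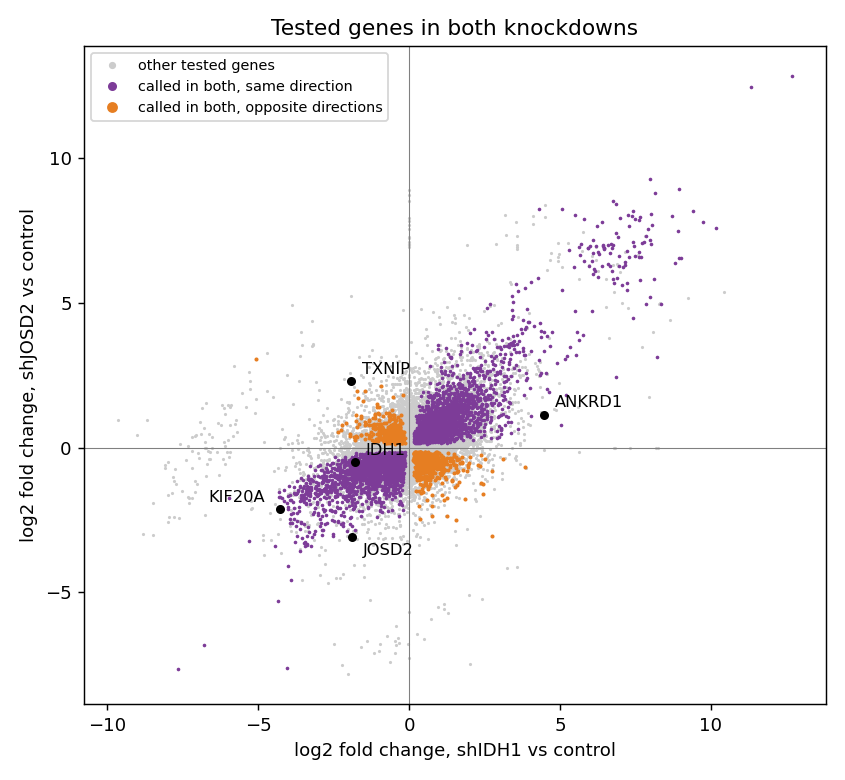
Log2 fold change against control in shJOSD2 cells (vertical axis) and in shIDH1 cells (horizontal axis) for each of the 21492 tested genes, 3 libraries per group. Purple points are the 5102 genes called in the same direction in both comparisons, orange points the 967 called in opposite directions, and black points mark 5 named genes. Fitted values beyond about 6 mostly belong to genes with a group at 0 counts and are not measured folds.

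**Figure D3:**
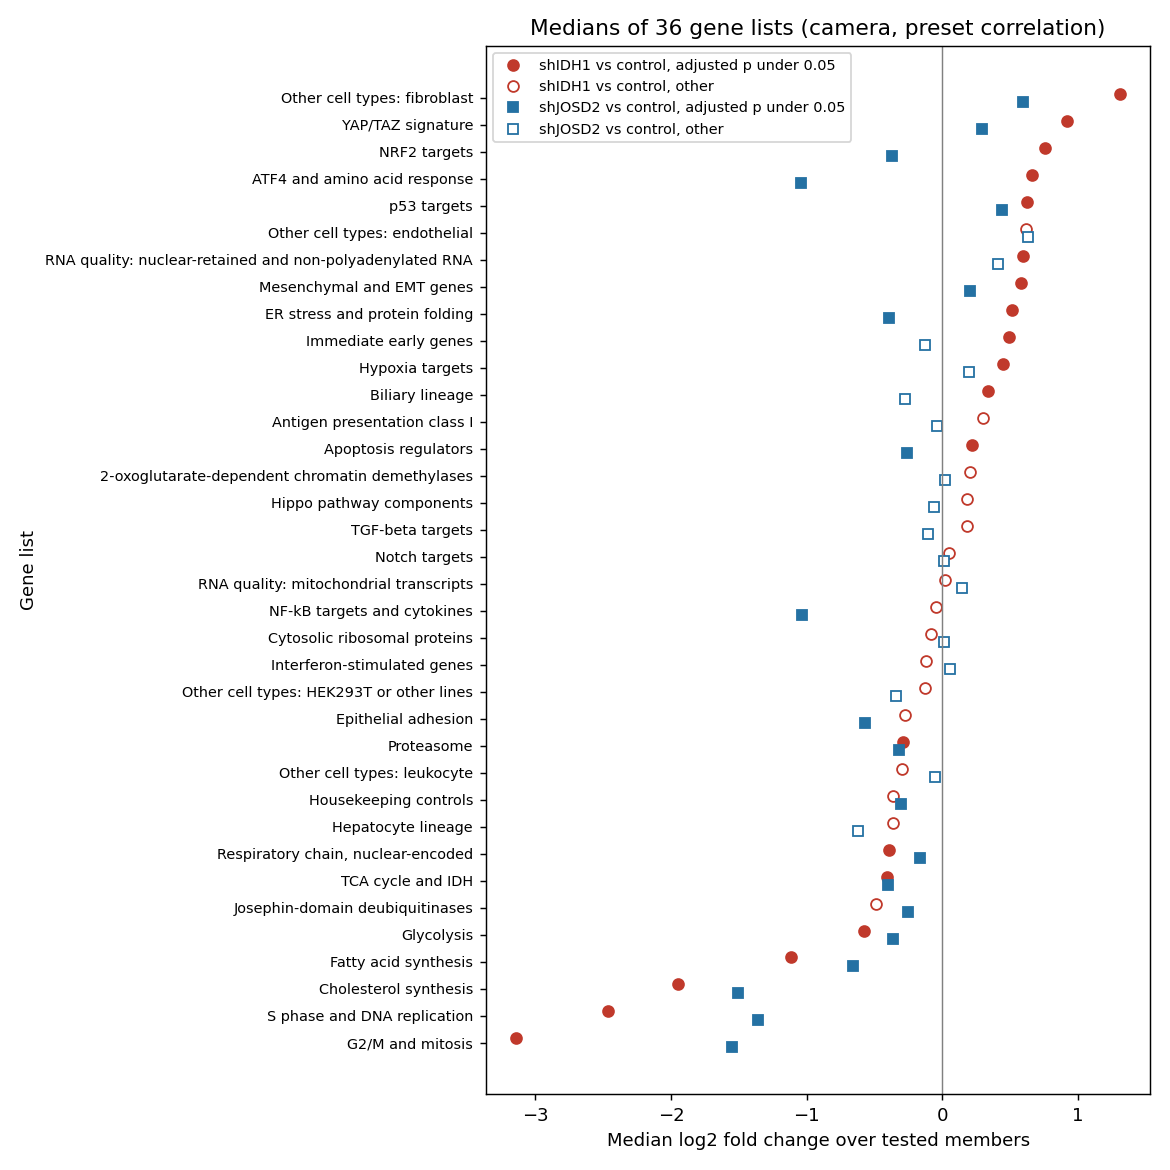
Median log2 fold change of the 36 gene lists in shIDH1 (red circles) and shJOSD2 cells (blue squares) against control. Filled symbols passed camera with its preset correlation at an adjusted p under 0.05, which fewer lists did with an estimated correlation. The G2/M list lay at -3.14 and -1.55, and the ATF4 list at 0.66 and -1.04.

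The direct comparison of shIDH1 with shJOSD2 asks where the depletions of IDH1 and JOSD2 differ. DDIT3 stood 7.29-fold higher in shIDH1 than in shJOSD2 cells, at 88.7 ± 18.4 against 13.5 ± 1.03 FPKM, and SPARC was higher by 4.26 ± 0.14 on the log2 scale (SE, n = 3 per group). BIRC3 was higher by 2.94 ± 0.12, at 5.10 ± 0.387 against 0.731 ± 0.0858 FPKM. AURKB and CDC20 were lower in shIDH1 cells, with log2 differences of -2.69 ± 0.17 and -2.31 ± 0.13. In all, edgeR's quasi-likelihood test called 9635 genes at a Benjamini-Hochberg adjusted p under 0.05, 4479 higher and 5156 lower in shIDH1 cells, 3043 of them at least 2-fold, and FPKM ranges did not overlap for 58.4% of genes against 10% by chance. Library sizes without TMM factors shifted the median of all genes to -0.21 and gave 3316 higher and 6653 lower, and limma on log2(FPKM + 1) gave 2958 higher and 5362 lower.

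Of 22 ATF4 and amino acid response genes 18 were higher in shIDH1 cells, 20 adjusted over the list alone, with a median of 1.53 (camera, adjusted p = 1.16e-15, and adjusted p = 0.224 with an estimated correlation). Of 16 ER stress genes 14 were higher and 1 lower, 15 adjusted over the list alone, with a median of 1.05 (camera, adjusted p = 1.18e-09, and adjusted p = 0.270 with an estimated correlation). Of 19 NRF2 targets 15 were higher and 1 lower, 16 adjusted over the list alone, with a median of 0.76 (camera, adjusted p = 3.16e-09, and adjusted p = 0.246 with an estimated correlation). Of 20 apoptosis regulators 13 were higher and 4 lower, 18 adjusted over the list alone, with a median of 0.52 (camera, adjusted p = 1.08e-05, and adjusted p = 0.0374 with an estimated correlation), and of 17 biliary genes 11 were higher and 3 lower, 14 adjusted over the list alone, with a median of 0.48 (camera, adjusted p = 2.80e-06, and adjusted p = 0.0374 with an estimated correlation). All 25 G2/M genes and 24 of 25 S phase genes were lower, 25 and 24 adjusted over the list alone, with medians of -1.60 and -1.27 (camera, adjusted p = 8.71e-25 and 1.25e-12, and adjusted p = 0.224 and 0.270 with an estimated correlation). Higher and lower members, respectively, numbered 10 and 3 of 23 Hippo components, 10 and 5 of 18 hypoxia targets, 9 and 2 of 18 NF-kB targets, 11 and 5 of 22 immediate early genes, 9 and 4 of 20 epithelial genes, and 10 and 2 of 16 mesenchymal genes. Their camera adjusted p values were 0.0214, 0.0252, 0.00536, 0.000300, 0.0205 and 0.000117, and with an estimated correlation adjusted p = 0.297, 0.246, 0.224, 0.224, 0.647 and 0.224. Adjusted over the list alone, 13, 15, 11, 16, 13 and 12 of these members passed. The lowest medians over 5 other scalings of these 6 lists were 0.03, 0.35, 0.34, 0.09, 0.33 and 0.19, in the same order, and those of the apoptosis and biliary lists 0.35 and 0.33. Cholesterol synthesis did not pass, with 11 genes lower and 5 higher of 24, 18 adjusted over the list alone (camera, adjusted p = 0.216, and 0.00139 without shIDH1 replicate 1). TGF-beta targets did not pass either, with 8 higher and 4 lower of 15, 12 adjusted over the list alone (camera, adjusted p = 0.0524). They were called in 6 of 9 tests with 1 library left out, at adjusted p = 0.0274 and 0.0264 without control replicates 1 and 2, 0.0216 and 0.0192 without shIDH1 replicates 2 and 3 and 0.0454 and 0.0456 without shJOSD2 replicates 1 and 2, and at 0.0229 with the lone control. The hepatocyte list (camera, adjusted p = 0.118) had 0.0353 and 0.0369 without control replicates 1 and 3 and 0.0123 with the lone control, and the respiratory chain list (camera, adjusted p = 0.0925) had 0.0412 without shJOSD2 replicate 1.

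Among called genes with separate FPKM ranges, the 5 ranked first by fitted change above shJOSD2 in shIDH1 cells were NPPB, DSCAS, LINC01594, FUT6 and NOP53-AS1, at least 5.02-fold to 9.69-fold higher. Those ranked first below were DMRT1, LINC01173, MYBPC1, TNFRSF8 and NHLH1, at least 9.37-fold to 14.5-fold lower, all against a group at 0 counts. None of these is shown to differ the most, and the measured difference of SPARC exceeds all 10 bounds.

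The YAP/TAZ signature, a list of 22 known target genes, asks about the transcriptional output of YAP1 and WWTR1. It rose in shIDH1 cells: 15 genes rose and 4 fell (AXL, F3, ASAP1 and NT5E), 19 adjusted over the list alone, with a median of 0.92. CCN2, a secreted matricellular protein, rose 7.50-fold to 397 ± 33.7 FPKM and CCN1 from 78.4 ± 5.86 to 250.5 ± 5.02, by 2.91 ± 0.10 and 1.67 ± 0.06 on the log2 scale (SE, n = 3 per group), while AXL, a receptor kinase, fell by 1.08 ± 0.06. Camera gave an adjusted p of 2.63e-12 for the list, and an adjusted p of 0.00716 with an estimated correlation. In shJOSD2 cells 12 genes rose and 4 fell (CRIM1, FOXF2, LATS2 and FJX1), 17 adjusted over the list alone, with a median of 0.29, ANKRD1 up by 1.14 ± 0.08, CCN2 up by 0.34 ± 0.09 and CRIM1 down by 1.18 ± 0.09. Camera gave an adjusted p of 0.0286 there, but adjusted p = 0.191 with an estimated correlation and 0.261 without CCN1, CCN2 and ANKRD1. The estimated correlations of the list were -0.0257 for shIDH1 and -0.0227 for shJOSD2, below the preset 0.01. A higher correlation among members thus does not account for the larger p values. Fry gave adjusted p = 6.68e-08 in shIDH1 and 0.000143 in shJOSD2 cells. Between the hairpins, 15 genes were higher and 4 lower in shIDH1 cells, 19 adjusted over the list alone, with a median of 0.92 (camera, adjusted p = 2.13e-10, and adjusted p = 0.0117 with an estimated correlation). YAP1 itself stood at 14.2 ± 1.03 FPKM in control and 15.1 ± 1.34 in shIDH1 libraries, and WWTR1 at 26.9 ± 3.21 in control, 27.1 ± 3.51 in shIDH1 and 28.9 ± 0.700 in shJOSD2 libraries (SD, n = 3 each). Neither passed the test against control, with log2 changes of 0.09 ± 0.08 and 0.01 ± 0.09 for shIDH1 and of -0.17 ± 0.08 and -0.04 ± 0.09 for shJOSD2. Between the hairpins YAP1 was higher in shIDH1 cells by 0.26 ± 0.08 (adjusted p = 0.0180, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with overlapping FPKM ranges. This call depended on the scaling, with a difference of 0.10 both by library sizes without TMM factors (adjusted p = 0.356, edgeR with Benjamini-Hochberg adjustment) and by limma on log2(FPKM + 1) (adjusted p = 0.297, limma with the same adjustment). It was also lost without shIDH1 replicate 1, shJOSD2 replicate 1 or shJOSD2 replicate 3 (adjusted p = 0.0763, 0.0852 and 0.0635).

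Some calls within the signature were not stable (adjusted p values from edgeR with Benjamini-Hochberg adjustment). In shJOSD2 cells those of CCN2, NUAK2, PTPN14 and RBMS3 were lost against control replicate 1 alone, at adjusted p = 0.380, 0.0779, 0.102 and 0.0802. There FOXF2 lost its call by library sizes, with the replicate block and without control replicate 1 or 2 or shJOSD2 replicate 1 or 2, at adjusted p = 0.0834, 0.0567, 0.0972, 0.0953, 0.115 and 0.110, and by limma on log2(FPKM + 1), at limma's adjusted p = 0.0526. IGFBP3 lost it with median-of-ratios factors, without control replicate 1 or 2, without shIDH1 replicate 2 or 3 and without shJOSD2 replicate 1, 2 or 3, at adjusted p = 0.0536, 0.115, 0.167, 0.0648, 0.0503, 0.0875, 0.0722 and 0.108. Without control replicate 2, PTPN14 and CCN2 had adjusted p values of 0.0706 and 0.0531, and PTPN14 had 0.0713 without shJOSD2 replicate 2. RBMS3 had 0.0575 without control replicate 3 and 0.0616 without shJOSD2 replicate 3. In shIDH1 cells PTPN14 was not called against control replicate 1 alone (0.119), without control replicate 2 (0.110) or without shIDH1 replicate 1 (0.130). Between the hairpins ARHGEF17 and TGFB2 lost their calls by library sizes (0.613 and 0.0614), and ARHGEF17 without shIDH1 replicate 2 or shJOSD2 replicate 2 or 3 (0.0583, 0.0758 and 0.0677).

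**Figure D4:**
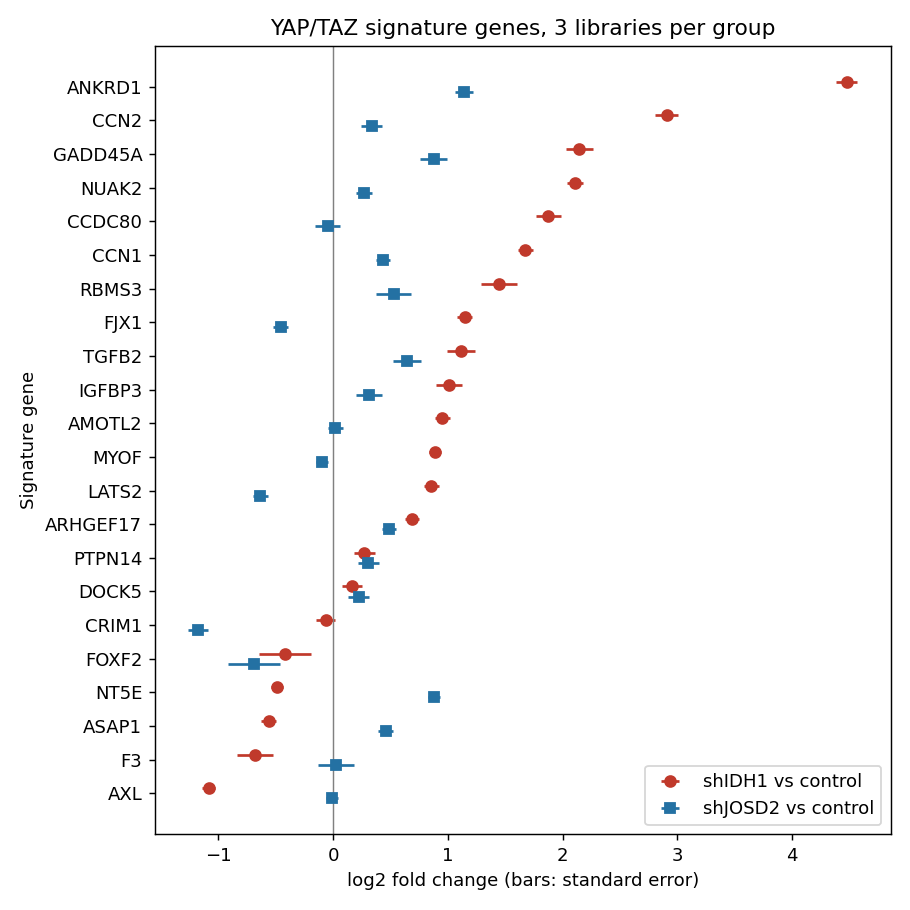
Log2 fold change against control (horizontal axis) with its standard error for the 22 signature genes in shIDH1 (red circles) and shJOSD2 cells (blue squares), 3 libraries per group. ANKRD1 lay at 4.48 and 1.14, and the medians of the list at 0.92 and 0.29.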

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

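The tests of the JOSD2 pattern, the lone control and the scaling by library sizes without TMM factors were chosen only after results were seen. Among the lists, 4 were called in opposite directions under the hairpins, with the difference itself called in the direct comparison. The median log2 difference between shIDH1 and shJOSD2 cells was 1.53 for the ATF4 and amino acid response list, 1.05 for the ER stress and protein folding list, 0.76 for the NRF2 targets list and 0.52 for the apoptosis regulators list. The lowest of these medians over 5 other scalings were 1.35, 0.83, 0.55 and 0.35, in the same order. With an estimated correlation, camera kept a call of the difference for apoptosis regulators (adjusted p = 0.0374) and not for the others (adjusted p = 0.224, 0.270 and 0.246 for the ATF4, ER stress and NRF2 lists). The calls against control were all lost with it, at adjusted p = 0.497 for the ATF4, ER stress and NRF2 lists and 0.176 for apoptosis regulators in shIDH1 cells, and at adjusted p = 0.348, 0.668, 0.596 and 0.191 for the ATF4, ER stress, NRF2 and apoptosis lists in shJOSD2 cells. The apoptosis call in shJOSD2 cells was also lost without control replicate 1 (camera, adjusted p = 0.0501). Fry, which does not set the members against other genes, called these lists in both comparisons with control, in the directions of camera. For the ATF4, ER stress, NRF2 and apoptosis lists its adjusted p values were 0.00345, 0.00317, 0.00145 and 3.62e-05 in shIDH1 cells. In shJOSD2 cells fry gave adjusted p = 0.00341, 0.0377, 0.0114 and 0.000204, in the same order.

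The YAP/TAZ signature was higher after IDH1 depletion although the title of the series describes mutant IDH1 as activating YAP/TAZ. The gene-level values do not tell mutant from normal IDH1 transcripts, and the signature measures RNA alone. The title's statement was therefore not tested. Scaling between libraries is argued against, since the lowest median over 5 other scalings was 0.88. Other RNA in control replicates 2 and 3 is argued against too, with a median of 0.94 against control replicate 1 alone, and so are GC content and transcript length, whose removal left a median of 0.92. A response of the cells to the hairpin stays open as a hypothesis, and it may be specific to IDH1 or come with this hairpin, which was not tested.

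JOSD2 was lower in the shIDH1 libraries. Mixing of shJOSD2 RNA into these libraries would need a share of 84.0%, and 42.6% of the 524 genes raised at least 4-fold by shJOSD2 lay below 0.5 of the level this share requires, which argues against it. TXNIP would have stood at 80.7 FPKM and stood at 4.65. Reads of an overlapping gene are argued against by 0 other genes of the table overlapping the span of JOSD2. A fall of JOSD2 transcripts that follows IDH1 depletion, and an off-target effect of the hairpin, may each account for it and were not separated.

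Each comparison of 3 with 3 libraries has 10 splits, of which 1, the real one, gave as many called genes in each comparison, too few splits for a share under 0.05. The real counts of 10769, 8237 and 9635 genes stood against highest values of 1, 0 and 2 in the other splits for shIDH1, shJOSD2 and the direct comparison. Each other split mixes libraries of both groups, so the difference between the groups enters the spread and few genes can pass. These low values therefore do not show what chance would give.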

How the results depend on the processing

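Counts divided by 4, library sizes without TMM factors and control replicate 1 as the lone control were chosen only after seeing the data. Limma on log2(FPKM + 1) was the test the design named for FPKM values. Of 526 results for named genes, chosen in part from these data, 420 kept their direction and side of the threshold under each alternative that gave them a value. Values were had for 321 of them with a mean FPKM of at least 5, 409 by limma, 476 with counts divided by 4, 513 from the 6 libraries of a comparison alone, and 526 under the others. Against the lone control 61 were weaker and 7 reversed. Over 11888 values under alternatives, 11418 were kept, 432 were weaker, 4 stronger and 34 reversed, and of 2412 counts of called list members 2263 stayed within 1.5 times. Called genes without 1 library ranged from 9724 to 10635 for shIDH1, 6939 to 8248 for shJOSD2 and 8430 to 9927 between hairpins. DESeq2 called 11147, 8732 and 9953 genes, and counts divided by 4 gave 10544, 8376 and 9801. Of all 10769 and 8237 genes called for shIDH1 and shJOSD2, limma on log2(FPKM + 1) also called 8268 and 5405, with 12396 genes tested. Library sizes without TMM factors also called 10656 and 6841 of them. A change of at least 2-fold left 4120, 2328 and 3043 genes and 1238 shared in direction, since fewer genes can pass. A mean FPKM of at least 5 left 5103, 4129, 4906 and 2639, with fewer genes tested, and the lone control left 3266 shared genes with fewer libraries.

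The YAP/TAZ list in shJOSD2 cells lost its call with an adjusted p of 0.0664 by limma on log2(FPKM + 1), 0.0638 on log2(FPKM + 0.1), 0.191 with an estimated correlation and 0.261 without CCN1, CCN2 and ANKRD1. The first of these fits was the test the design named for FPKM values. Among the log2 changes that reversed, those of IDH2, WWTR1, JOSD1 and YAP1 passed the test neither before nor after. Without TMM factors the median of all genes in shJOSD2 cells moved from 0.03 to 0.18. JOSD1 and WWTR1 moved alongside it there, each from -0.04 to 0.11. The cause of the other reversals was not tested. In shIDH1 cells IDH2 was 0.0578 with the FPKM minimum, 0.0779 on quantile-normalized values and 0.0765 against the lone control, and -0.10 to 0.0203 without 1 library. WWTR1 there was -0.00167 on log2(TPM + 1), and -0.0919 to 0.11 without 1 library. In shJOSD2 cells JOSD1 was 0.0889 with the FPKM minimum, 0.10 and 0.11 by limma with pseudocounts of 1 and 0.1, 0.0362 on TPM, 0.14 on quantile-normalized values and 0.11 by library sizes. WWTR1 was 0.0890, 0.11, 0.11, 0.0387, 0.16 and 0.11 under the same settings, 0.0138 against the lone control, and -0.10 to 0.0574 without 1 library. YAP1 was 0.00666 on quantile-normalized values. Between the hairpins WWTR1 was -0.10 by limma with either pseudocount, -0.0404 on TPM, -0.0263 on quantile-normalized values and -0.10 by library sizes, and -0.0468 to 0.10 without 1 library. Of the named genes called against all 3 control libraries, 5 changed sign in the fit with the lone control, which rests on 1 control library. Other called genes were not counted in this way. Of the 55 genes at least 4-fold higher in control replicates 2 and 3 than in replicate 1, 39 were called for shIDH1 and 32 for shJOSD2 against all 3 control libraries. For APOA2 in shIDH1 cells the fitted value went from -4.56 to 5.24, which is no measured reversal, since it stood at 0 FPKM in control replicate 1 and at 0, 0.171 and 0 in the shIDH1 libraries. The others were ALB from -2.50 to 0.59, APOA1 from -2.93 to 0.45, ESRP1 from -2.05 to 0.40 and TTR from -2.92 to 1.47 in shJOSD2 cells, where ESRP1 and TTR stood at only 0.0565 and 0.0376 FPKM in control replicate 1.

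With the replicate number as a block, 10416, 7823 and 9296 genes were called for shIDH1, shJOSD2 and between hairpins. The deviations of same-numbered libraries correlated with r of -0.09 to 0.08, against -0.11 to 0.17 for other numbers, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken to pair the libraries.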

Other observations

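The KEGG, SRF, hepatocyte and change of state tests in this part were chosen only after results were seen. Among 308 KEGG terms annotated in the table, genes raised at least 2-fold in shIDH1 cells were over-represented in ECM-receptor interaction, with 30 of 71 genes against 6.93 expected (hypergeometric adjusted p = 1.50e-10), and in complement and coagulation cascades, with 26 of 62 against 6.05 (adjusted p = 2.29e-09). COL4A1, a basement membrane collagen, rose from 12.3 ± 1.20 to 58.8 ± 0.869 FPKM (SD, n = 3), ITGA10, an integrin, from 0.782 ± 0.179 to 11.3 ± 0.330 and coagulation factor F5 from 3.57 ± 0.451 to 19.2 ± 1.38. Genes lowered at least 2-fold in shIDH1 cells were most over-represented in DNA replication, with 28 of 36 genes against 4.27 expected (hypergeometric adjusted p = 2.74e-17). Cell cycle came next, with 48 of 120 against 14.2 (adjusted p = 2.80e-13). DNA repair and splicing terms followed, and a repair effect separate from replication was not tested. The Fanconi anemia pathway held 25 of 54 genes against 6.41 expected (adjusted p = 2.87e-08), base excision repair 17 of 33 against 3.92 (adjusted p = 2.17e-06) and the spliceosome 36 of 131 against 15.5 (adjusted p = 3.05e-05). BRCA1 fell by 2.38 ± 0.13 on the log2 scale, PARP1 by 1.74 ± 0.06 and the splicing factor gene SF3A3 by 2.20 ± 0.09. In shJOSD2 cells, genes lowered at least 2-fold were most over-represented in cell cycle, steroid biosynthesis and DNA replication (hypergeometric adjusted p = 7.91e-10, 3.01e-07 and 8.03e-05). IL-17 signaling followed, with 15 of 71 against 4.36 expected (hypergeometric adjusted p = 0.00148), where HSP90AB1 fell from 717 ± 11.3 to 213 ± 8.02 FPKM.

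Some hepatocyte genes were higher in control replicates 2 and 3 than in replicate 1, at least 4-fold in both for 7 of the 20 list members. APOE, chosen after its values were seen, stood at 1.09, 12.2 and 13.7 FPKM in control replicates 1, 2 and 3, while FGB stood at 1.53, 1.72 and 1.87. GSTP1 and LDHB, chosen in the same way, rose like APOE, at 0.495, 6.69 and 8.12 and at 0.384, 4.56 and 5.19 FPKM. HBA2, a globin gene chosen in the same way, did not follow this pattern, at 1.73, 12.6 and 0.471 FPKM in these libraries and 11.5 in shJOSD2 replicate 3, and the cause was not tested. RNA from hepatocyte-like cells in control replicates 2 and 3 may account for the 55 genes at least 4-fold higher in both. Of the 20 list members 7 were among these genes, against 55 of all 36225 genes of the table at any level of expression. The kind of cell was not tested. The explanation by added RNA stays open, and the count of raised members cannot decide it. A member already abundant in replicate 1, such as SERPINA1 at 33.6 FPKM, would need much added RNA to rise 4-fold. An earlier test, of the spread between these 2 libraries over the raised genes, gave 3.52 times that of other genes by SD and 1.20 times by scaled median absolute deviation. It decides nothing, because the genes were selected in replicate 2, and the count of list members replaced it with bounds set after the count was known. A change of state of the RBE cells cannot be told apart from such added RNA, because 10 genes were at least 4-fold lower in both, but a minority of cells in another state would also add transcripts alone.

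A general rise of SRF cytoskeletal targets was tested as a hypothesis for CCN1, CCN2 and ANKRD1, which SRF and YAP/TAZ both can regulate. For these targets alone it is argued against: 19 SRF cytoskeletal targets outside the signature had a median log2 change of -0.70 in shIDH1 cells, 3 called higher and 12 lower (camera, p = 0.000128, and p = 0.0843 with an estimated correlation). A rise of other SRF targets was not tested.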
